A study of Boehmeria nivea with 4 samples.

How the data were processed

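RNA sequencing of whole ramie plants was compared between 2 control plants and 2 plants kept for 20 days in soil with 100 mg cadmium per kg, each an individual potted plant and 1 paired-end Illumina library. The authors deposited, for each unigene and library, an estimated count (an expected read count, not scaled for depth; 13.6% to 15.8% of the values were not whole numbers). They also deposited an FPKM value (fragments per kilobase of unigene and sequencing depth), per the file headers and the values. The unigene identifiers carry assembly component numbers. The assembler, the aligner and the counting program are not given in the sources used here, and DESeq, with no version, is the only tool the submitters' notes name. Of 56932 unigenes, with a median length of 405 bases (201 to 17472), 1478 had 0 counts in all libraries and 26683 carried some annotation. No genome was used, so no positions are given.

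Estimated counts were rounded to whole numbers before every test on counts. Unigenes with low counts were removed with edgeR's filterByExpr, which left 22257 holding 99.6% of the counts. Libraries were scaled by TMM (factors 0.982, 1.008, 1.008 and 1.001), and cadmium was compared with control by edgeR's quasi-likelihood F-test (two-sided, group as the only term, no robust option), with Benjamini-Hochberg adjusted p under 0.05. The biological coefficient of variation was 0.157. The SE of a log2 fold change was derived from this test, as its absolute value divided by the square root of F. It is therefore not a measure of precision separate from the p-value. Levels of tested unigenes are counts-per-million (CPM) on TMM-scaled library sizes, as means with the SD of 2 plants, while CPM of groups of organisms and of virus-like unigenes are per total count. For unigenes at 0 in both controls the fold is a lower bound against a floor of 3 counts over the control group, so with a control library left out it falls with the control total. With 1 to 3 control counts the ratio of counts is given with its 95% counting interval. A count of 0 in a library allows up to 0.146, 0.137, 0.172 and 0.15 CPM in control 1, control 2, cadmium 1 and cadmium 2. Such intervals and floors cover counting error only.

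Gene lists were text patterns on 1 description per unigene, taken from Swiss-Prot (19674 unigenes), else the NCBI protein (275), KEGG orthology (113), KOG (165) or Pfam (4254) column. The 20 lists were metal chelation, metal transport, glutathione and glutathione S-transferases, sulphur assimilation, reactive oxygen scavenging, class III peroxidases, heat shock and chaperones, ethylene, jasmonate, abscisic acid and dehydration, stress transcription factors, phenylpropanoid and lignin, cellulose and cell wall, pathogenesis-related, photosynthesis, root, stem fibre and xylem, cell division, ribosomal proteins, and virus or other organism. Each was tested with limma's camera on log2 CPM with a preset correlation of 0.01, adjusted over the 20 lists. It was tested again with an estimated correlation and with fry, which tests whether members move, on balance, in 1 direction. Members were also adjusted over the list alone. Another 5 lists (seed storage and oil bodies, floral organ identity, cutin and wax, starch synthesis, flavonoid synthesis) were written after the calls had been seen and adjusted as a family of their own. Unigenes were assigned to fungi and arthropods by the genus of their best nucleotide or protein match.

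The groups, the tests, the 20 lists, the alternative settings and the rule for named unigenes were chosen before the data were examined. The rule took, among unigenes past an adjusted p of 0.05 with both cadmium plants beyond both controls and a mean log2 CPM of at least 1, the 10 largest rises and the 10 largest falls. To these it added up to 3 called members of each list with the smallest p, which gave 23 unigenes in all.

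Unigenes seen in 1 group only had at least 10 counts in both libraries of a group and 0 in both of the other. Agreement of libraries was measured as Pearson's correlation across unigenes of log2(CPM + 1), the SD of log2 differences and a chi-square of the counts. Pairs of sub-components were compared with 10000 random pairs matched on expression. The procedure was tested on simulated data with 21579 unigenes, where edgeR recovered 54 of 100 changes of 2-fold and 93 of 100 of 4-fold, with 10 false calls and 0 of the wrong sign. On the same data DESeq2 recovered 58 and 91, with 14 false calls. The changes were set only in unigenes with a mean above 1 CPM, so recovery below that level was not measured.

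Alternatives were DESeq2, limma-voom, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1) for unigenes with FPKM of at least 0.3 in 2 libraries, 3 other scalings, no filter and a filter of 1 CPM in 2 libraries. Others were robust fitting, the plant number as a block, each library left out, and stricter thresholds. The pairing with crossed plant numbers, the removal of fungal and arthropod unigenes, the ratios, the bounds and the seed list's median with each library left out, and the 5 further lists were chosen after the data were seen. Annotation of gene ontology terms was not used here. The tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, the data.table package in version 1.17.8, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.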

Results

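RNA was sequenced from whole ramie plants (Boehmeria nivea, a bast fibre crop, source Qingyezhuma) grown in pots, with root, stem, leaf and shoot of a plant pooled as 1 sample. The design set 2 control plants against 2 plants held for 20 days in soil brought to 100 mg cadmium per kg, all 60 days old at sampling. The labels give each replicate as a separate potted plant. The series title gives the question: how the ramie transcriptome responds to cadmium, a toxic heavy metal. The tables listed 56932 unigenes, which are transcript sequences assembled without a reference genome, so no chromosome position is given. Total estimated counts were 20480938 and 21963677 in control 1 and control 2, and 17430218 and 20007049 in cadmium 1 and cadmium 2. Counts above 0 were recorded for 46212, 45862, 43224 and 46668 unigenes in the same order, and for 44919, 44091, 43224 and 45565 after thinning to the smallest total. The 10 most abundant unigenes took 4.36%, 3.59%, 3.34% and 3.81% of the counts, the top 100 took 16.1%, 14.5%, 14.1% and 15.2%, and the top 1000 took 44.9%, 43.4%, 43.7% and 44.3%. The small chain of Rubisco, the carbon-fixing enzyme of photosynthesis, was the most abundant unigene in 3 of the 4 libraries (comp32524_c0).

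In the cadmium plants, seed storage protein transcripts, a late embryogenesis abundant protein, a glutathione S-transferase and an amino acid transporter rose, while unigenes for a tyrosine decarboxylase, a phospholipase, the GDSL esterase/lipase EXL3, a xylanase and a pectinesterase fell. Of 22257 unigenes tested, 32 changed at an adjusted p under 0.05, 16 higher and 16 lower in cadmium, and all 32 changed by at least 1 on the log2 scale. Sucrose-binding protein (comp47085_c0), a relative of the vicilin storage globulins, had 0 counts in both controls and 321 and 317 counts in the cadmium plants, at least 241-fold higher against a floor of 3 counts over the control group (adjusted p = 0.00958). A vicilin-like unigene (comp43760_c0) had 0 counts in both controls and 186 and 337 in the cadmium plants, at least 198-fold higher. The 11S globulin seed storage protein 2 (comp47414_c0) had 0 and 2 counts in the controls and 250 and 1283 in the cadmium plants, a ratio of 869 with a 95% counting interval of 240 to 7180 (adjusted p = 0.049). The ratio was 1360 without cadmium 1, 304 without cadmium 2 and 450 without control 1, and without control 2, which held both control counts, the level was at least 280-fold higher. Its adjusted p was 0.202 with limma-voom, 0.0526 with upper quartile scaling and 0.0605 with robust fitting.

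The F-box protein PP2-B15 (comp42180_c0) rose from 4 counts in the controls, 2 in each, to 203 in the cadmium plants, a ratio of 57.5 with a 95% counting interval of 22.1 to 213. Its level in the cadmium plants was 5.45 ± 0.687 counts-per-million (CPM; SD, n = 2). Late embryogenesis abundant protein Lea5 (comp49114_c0), of a protein family that accumulates in maturing seeds and under water deficit, rose 3.28-fold from 151.9 ± 4.41 to 498.7 ± 40.6 CPM (log2 fold change 1.72, SE 0.15; adjusted p = 0.0254). Glutathione S-transferase L3 (comp36595_c0), of a family that joins glutathione to other compounds or reduces them with it, rose 3.9-fold from 45.7 ± 8.41 to 178.2 ± 40.1 CPM (adjusted p = 0.0329). Lysine histidine transporter-like 8 (comp45770_c0), of an amino acid transporter family, rose 4.64-fold from 5.75 ± 0.693 to 26.7 ± 5.58 CPM. The other 5 of the 10 largest rises had no description. Of these, comp38766_c0 and comp35475_c0 were at 0 in both controls and at least 348-fold and 58.2-fold higher in cadmium. These bounds were 202 and 80.4 without cadmium 2, and 475 and 38.9 without cadmium 1. Rises of 4.93-fold, 4.9-fold and 4.64-fold were found for comp39615_c0, comp36050_c0 and comp51849_c0.

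Tyrosine/DOPA decarboxylase 2 (comp42435_c0), which turns tyrosine and DOPA into tyramine and dopamine, fell by 1.96 on the log2 scale (SE 0.15) from 94.3 ± 11.3 to 24.2 ± 1.31 CPM (adjusted p = 0.0182). A pair of unigenes described as GDSL esterase/lipase EXL3 fell by 1.91 (comp45328_c0) and 1.61 (comp40907_c0). Phospholipase A1-IIgamma (comp49781_c1), which releases fatty acids from membrane lipids, fell from 106.9 ± 15.4 to 33.6 ± 0.362 CPM. Protein ASPARTIC PROTEASE IN GUARD CELL 2 (comp48216_c1) fell by 1.88, from 259 ± 2.84 to 70.3 ± 18 CPM. Falls of other named unigenes were those of endo-1,4-beta-xylanase C (comp39560_c0, 3.87-fold), (R)-mandelonitrile lyase 1 (comp39115_c0, 3.81-fold), a putative invertase inhibitor (comp42094_c0, 3.71-fold) and probable pectinesterase/pectinesterase inhibitor 54 (comp46325_c0, 2.3-fold), of a family that removes methyl groups from wall pectin. The log2 fold change of pectinesterase/pectinesterase inhibitor 54 was -1.20, and it was -1.14 without cadmium 1 (adjusted p = 0.0691) and -1.25 without cadmium 2 (adjusted p = 0.0573), so its size changed little while the adjusted p passed 0.05. The unigene comp32257_c0 had no description and fell 3.56-fold. The short unigene comp17780_c0 fell 2.87-fold, and its description was a Pfam domain name alone (Potato leaf roll virus readthrough protein). Its log2 fold change was -1.52, and -1.47 without cadmium 1 (adjusted p = 0.0521).

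**Figure D1:**
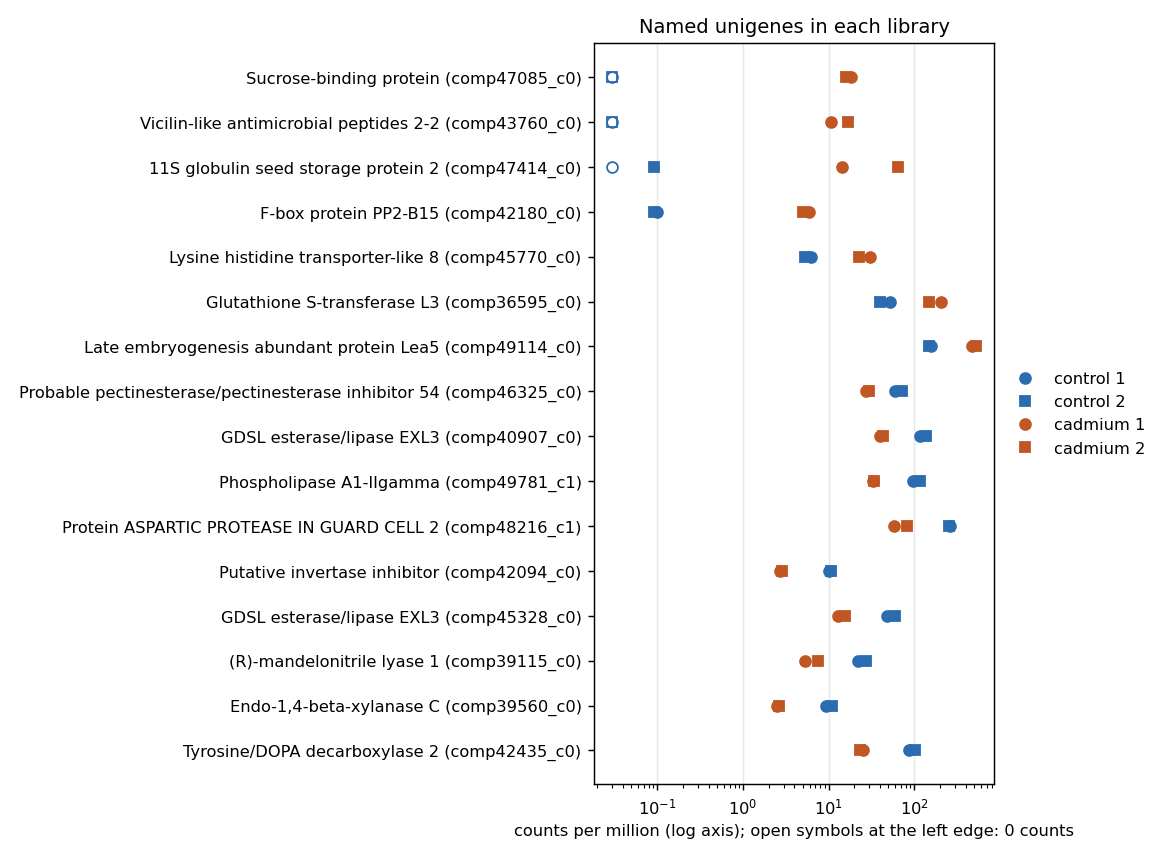
Values in CPM (log axis) of the 16 named unigenes with a description other than a viral domain name, in each of the 4 libraries; circles are plants numbered 1, squares plants numbered 2, and open symbols at the left edge stand for 0 counts. Both cadmium plants lie on the same side of both control plants in every row, for example 25.1 and 23.3 against 86.3 and 102.3 for tyrosine/DOPA decarboxylase 2. The naming rule required this of the largest rises and falls, so it is no separate result.

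All 32 calls came from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and all 32 were among the 461 unigenes called by DESeq2 (232 higher, 229 lower). The count differed between settings and with a library left out. Limma-trend on log2(FPKM + 1) called 0 (4444 of 49077 unigenes at an unadjusted p under 0.05), with the input and the filter changed as well as the tool. DESeq2 was run on 55454 unigenes, without edgeR's filter. These differences can therefore not be put down to the tool alone. With edgeR, 2222 unigenes had an unadjusted p under 0.05, 1111 in each direction. Both cadmium plants lay above both controls for 4539 of the tested unigenes and below them for 4289, together 39.7%, where chance gives 33.3%. Unigenes are not independent replicates and the other splits of the libraries were not counted, so this difference is not a test of cadmium. Of the 23 named unigenes, 8 did not pass with limma-voom, 10 with upper quartile scaling and 4 with library totals. A single value compared between groups of 2 cannot reach an exact permutation p below 0.333.

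The tested unigenes were also grouped by the 20 lists fixed before the data were examined. Camera called 4 of the lists, 2 up and 2 down, at its preset correlation of 0.01. With an estimated correlation 0 lists were called, and with fry 0, and in both the number of lists at an unadjusted p under 0.05 was 0. Over all tested unigenes, edgeR called 1 member in each of 4 lists and 0 in the other 16 lists, which held 4 to 56 members each at an unadjusted p under 0.05 and 1 to 7 members each called by DESeq2. The list members named from here on, other than those already named above, such as Lea5, glutathione S-transferase L3, pectinesterase/pectinesterase inhibitor 54 and comp17780_c0, were chosen after their values were seen.

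Genes for metal-binding molecules were called higher as a list by camera at its preset correlation, but not with an estimated correlation or with fry. Of 40 tested members of the metal chelation list, 26 had a positive log2 fold change, with a median of 0.16 (camera adjusted p = 0.0277), and the list's adjusted p was 0.683 with an estimated correlation. Adjusted over the list alone, 3 members rose and 1 fell. Nicotianamine synthase (comp40955_c0), which makes the metal chelator nicotianamine, rose by 1.53 (SE 0.22) from 25.4 ± 1.07 to 73.2 ± 23.7 CPM (adjusted p = 0.00433 over the list alone), and a further nicotianamine synthase (comp53954_c0) rose by 1.26 (SE 0.30). Of 6 tested metallothioneins, which are cysteine-rich metal-binding proteins, 3 had a positive and 3 a negative log2 fold change (median 0.047). Among them, metallothionein-like protein type 2 (comp40839_c0) had 1 count in the controls against 65 and 375 in the cadmium plants, a ratio of 499 with a 95% counting interval of 89.1 to 19700. The ratio was 796 without cadmium 1, 158 without cadmium 2 and 258 without control 1, and without control 2 the level was at least 80.2-fold higher. The 11S globulin (comp47414_c0) was likewise near 0 in the controls, with 250 and 1283 counts in cadmium 1 and cadmium 2, while sucrose-binding protein (comp47085_c0) had 321 and 317. Heavy metal-associated isoprenylated plant protein 26 (comp51468_c0) fell from 22 ± 6.73 to 11 ± 0.617 CPM, 1 of 21 tested unigenes with that description, of which 13 had a positive and 8 a negative log2 fold change and 0 rose when adjusted over the list alone. The median of log2 CPM differences was 0.17 with all libraries, 0.24 without control 1, where the list was not called (adjusted p = 0.0775), and 0.17 without cadmium 2, where it was not called either (adjusted p = 0.185).

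Metal transporters did not move as a list. Of 78 tested members, 38 had a positive and 40 a negative log2 fold change (camera adjusted p = 0.571), and 0 passed when adjusted over the list alone, against 13 at an unadjusted p under 0.05 and 3 called higher by DESeq2. The median was -0.013, the mean 0.076 and the direction of the test up, and the median of log2 CPM differences was -0.008 with TMM scaling and 0.006 with library totals only. The cadmium/zinc-transporting ATPase HMA2 (comp50695_c0), a pump that exports these metals from cells, stood at 80.1 ± 6.21 CPM in controls and 132.3 ± 26.8 in cadmium (adjusted p = 0.0955 over the list alone).

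Genes of sulphur uptake and reduction included 2 of 30 members that rose when adjusted over the list alone. They were 5'-adenylylsulfate reductase 1 (comp44940_c1), which reduces activated sulphate to sulphite, from 239.3 ± 8.2 to 476.6 ± 30 CPM (log2 fold change 0.99, SE 0.15; adjusted p = 0.00679 over the list alone), and sulfate transporter 3.1 (comp32473_c0), from 129.3 ± 0.186 to 222.4 ± 11.3 CPM. The sulphur list as a whole had a median of 0.050 (camera adjusted p = 0.116). Of 68 members of the glutathione list, 3 rose when adjusted over the list alone, the L3 form above, glutathione S-transferase U10 (comp42929_c0, 1.18, SE 0.17) and glutathione transferase GST 23 (comp40680_c0, 2.01, SE 0.40), and the list's median was 0.050 (camera adjusted p = 0.116, and 0.0392 without control 2).

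Class III peroxidases, secreted enzymes that act on wall phenolics, included 8 of 55 members that rose and 0 that fell when adjusted over the list alone, against 3 with a negative fold change at an unadjusted p under 0.05 and 0 called lower by DESeq2. Peroxidase E5 (comp41607_c0) rose by 0.92 (SE 0.13) from 76.8 ± 1.84 to 144.9 ± 8.58 CPM, peroxidase 24 (comp23373_c0) by 1.88 (SE 0.28) and peroxidase 72 (comp43370_c0) by 0.88 (SE 0.20). The peroxidase list had a median of 0.14 and was not called (camera adjusted p = 0.0647). It was called without control 2 (adjusted p = 0.00267), and its median of log2 CPM differences was -0.039 without control 1, where control 1 lay 0.20 below the mean of the 4 libraries. Among 82 genes of reactive oxygen scavenging, 1 fell when adjusted over the list alone, the chloroplast copper-zinc superoxide dismutase (comp38158_c0, from 204.6 ± 9.57 to 116 ± 6.23 CPM), an enzyme that removes superoxide. Of 11 tested superoxide dismutases, 7 had a positive and 4 a negative log2 fold change. The copper-zinc form 4A (comp41066_c0) had 0 counts in both controls and 10 and 78 in cadmium 1 and cadmium 2. It was at least 33.3-fold higher, and at least 8.12-fold without cadmium 2 (adjusted p = 0.12 over the list alone with all libraries). The scavenging list had 41 positive and 41 negative members, a median of -0.008, a mean of 0.064 and a test direction of down (camera adjusted p = 0.809), which was up without control 1 or cadmium 1 (adjusted p = 0.678 and 0.326).

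Phenylpropanoid and lignin genes, which make the phenolic building blocks of lignin and flavonoids, were higher as a list in the cadmium plants. Of 115 tested members, 81 had a positive log2 fold change, with a median of 0.19 (camera adjusted p = 0.000826), and the list's adjusted p was 0.683 with an estimated correlation. Without control 1 its camera adjusted p was 0.0775, with a median of log2 CPM differences of 0.16 against 0.19 with all libraries. Adjusted over the list alone, 1 member rose, a unigene described as 4-coumarate--CoA ligase-like 10 (comp39271_c0), by 1.86 (SE 0.27) from 41.97 ± 5.01 to 152.2 ± 60.9 CPM. It is in the list by the text of its description, and whether it acts in this pathway was not tested. Of 15 tested unigenes described as 4-coumarate--CoA ligases, 9 had a positive and 6 a negative log2 fold change. Caffeic acid 3-O-methyltransferase (comp38115_c0), an enzyme of lignin monomer synthesis, had a log2 fold change of 0.79 (SE 0.20) and phenylalanine ammonia-lyase (comp39624_c3), the entry enzyme of the pathway, 0.51 (SE 0.15), and both had an adjusted p of 0.106 over the list alone.

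Cell wall genes moved both ways. Adjusted over the list alone, 3 of 205 members rose and 10 fell, and the list's median was 0.027, its mean -0.045 and its test direction down (camera adjusted p = 0.943), which was up without control 2 or cadmium 2 (adjusted p = 0.616 and 0.356). Of the expansins, which loosen walls, 3 unigenes fell, expansin-A8 (comp37435_c4, by 1.44, SE 0.20, and comp24048_c0, by 0.72, SE 0.16) and expansin-A2 (comp37435_c3, by 1.34, SE 0.18), out of 18 tested expansins of which 10 had a positive log2 fold change. An exopolygalacturonase (comp46232_c0) fell from 14.3 ± 5.28 to 3.02 ± 1.12 CPM and probable pectinesterase/pectinesterase inhibitor 41 (comp44937_c1) from 14.6 ± 1.03 to 4.36 ± 1.64 CPM. The 3 members that rose were among 39 described as polygalacturonases, which cut pectin and were split 20 to 19 between positive and negative values, with rises of 1.10 (comp40590_c0, SE 0.25), 1.05 (comp40590_c1, SE 0.17) and 1.01 (comp45453_c0, SE 0.23). Of these comp40590_c1 had the highest level, from 26.7 ± 4.91 to 55.1 ± 6.22 CPM. The unigenes comp40590_c1 and comp40590_c0 are parts of the same assembly component, as are comp37435_c4 and comp37435_c3.

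Of the pathogenesis-related genes, 2 of 109 rose and 1 fell when adjusted over the list alone. A basic pathogenesis-related protein 1 (comp39449_c0) rose by 1.76 (SE 0.31) and an endochitinase (comp46475_c0) from 100.1 ± 18.4 to 194.9 ± 19.3 CPM, while a basic glucan endo-1,3-beta-glucosidase (comp39776_c0) fell by 1.79 (SE 0.34). The median of this list was 0.093 (camera adjusted p = 0.0647, and 0.00903 without control 2). In the abscisic acid and dehydration list, 3 of 86 members rose when adjusted over the list alone, Lea5 and a pair of late embryogenesis abundant unigenes at 0 in both controls, comp35113_c0 (at least 21.2-fold higher) and comp33586_c0 (at least 12.1-fold higher). Its members were split 43 to 43 between positive and negative values (camera adjusted p = 0.567). Among them, 10 were described as late embryogenesis abundant, 9 with a positive and 1 with a negative log2 fold change (median 0.47). Of 173 heat shock and chaperone members, 2 rose when adjusted over the list alone, a DnaJ homolog (comp41921_c0, 0.0907 ± 0.128 to 2.38 ± 0.0288 CPM) and an 18.2 kDa class I heat shock protein (comp31294_c0, at least 38.5-fold higher), and the list's median was 0.021 (camera adjusted p = 0.809).

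Of 307 stress transcription factors, 1 rose when adjusted over the list alone, MYB3 (comp41485_c0), by 1.19 (SE 0.15) from 30.7 ± 4.36 to 70.2 ± 5.96 CPM, and the list's median was 0.057 (camera adjusted p = 0.107). In the ethylene list 0 of 102 members passed when adjusted over the list alone, against 21 at an unadjusted p under 0.05 and 3 called by DESeq2, and its median was 0.090 (camera adjusted p = 0.0647, 0.035 without control 2 and 0.0429 without cadmium 1). Its smallest p belonged to an ACC oxidase homolog (comp15136_c0), at 71.4 ± 1.9 and 126.8 ± 25.9 CPM in control and cadmium. In the jasmonate list 0 of 37 passed, against 8 at an unadjusted p under 0.05 and 2 called by DESeq2, and its median was 0.11 (camera adjusted p = 0.393). Jasmonate O-methyltransferase (comp44289_c0) stood at 39.7 ± 4.81 CPM in controls and 24.2 ± 1.23 in cadmium (adjusted p = 0.061 over the list alone).

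Photosynthesis genes, fixed as leaf tissue markers, were lower as a list in the cadmium plants. Of 65 tested members, 54 had a negative log2 fold change, with a median of -0.28 (camera adjusted p = 0.00401), and the list's adjusted p was 0.712 with an estimated correlation. Rubisco activase (comp46859_c0), with a log2 fold change of -0.72 (SE 0.27), stood at 4619 and 3083 CPM in the controls and 1998 and 2681 in the cadmium plants. A chlorophyll a-b binding protein (comp41251_c0) stood at 4911 and 3453 against 2194 and 3301 CPM. Adjusted over the list alone, the 1 member that passed was a low-level Rubisco small chain (comp20210_c0), which rose by 1.48 (SE 0.27). The list's members deviated from their own means by a median of 0.31 in control 1, -0.049 in control 2, -0.38 in cadmium 1 and 0.067 in cadmium 2. The median of log2 CPM differences went from -0.29 to -0.085 without control 1 (adjusted p = 0.735) and to -0.086 without cadmium 1 (adjusted p = 0.44), and to -0.44 without control 2 (adjusted p = 1.34e-06) and -0.53 without cadmium 2 (adjusted p = 7.46e-05). Unigenes with best matches to listed genera of Dothideomycetes, a class of fungi that includes leaf dwellers, took 857.2 and 391.1 CPM in control 1 and control 2 and 398.5 and 839.5 CPM in cadmium 1 and cadmium 2. Within their groups, control 1 and cadmium 2 held the higher values of both the photosynthesis list and the Dothideomycetes unigenes. Unigenes of another class of fungi, Agaricomycetes, took 58.3 and 90.9 CPM in control 1 and control 2 and 28 and 36.3 CPM in cadmium 1 and cadmium 2.

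The other tissue marker lists were not called. Of 67 root marker members, which included nitrate and phosphate transporters, 3 rose and 1 fell when adjusted over the list alone (median 0.063; camera adjusted p = 0.439). Nitrate transporter 1.5 (comp40103_c2), which loads nitrate into the xylem, rose by 1.35 (SE 0.30), and aquaporin TIP2-1 (comp37557_c0), a water channel, fell from 44.4 ± 4.27 to 27.2 ± 1.77 CPM. In the stem fibre and xylem list 0 of 36 members passed, against 4 at an unadjusted p under 0.05 and 2 called by DESeq2 (median 0.026; camera adjusted p = 0.809).

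Cell division genes were lower as a list in the cadmium plants. Of 176 tested members, 122 had a negative log2 fold change, with a median of -0.11 (camera adjusted p = 0.00127), and the list's adjusted p was 0.683 with an estimated correlation. Kinesins made up 51 of these members, of which 47 had a negative and 4 a positive log2 fold change (median -0.338). Adjusted over the list alone, 3 members fell, kinesin-related protein 11 (comp48552_c1, by 0.79, SE 0.14), kinesin KIF22 (comp36339_c0, by 1.26, SE 0.22) and histone H1.2 (comp49343_c0, from 192 ± 4.15 to 117.9 ± 1.86 CPM). The median of log2 CPM differences was -0.12 with all libraries, -0.10 without control 2 and -0.061 without cadmium 2, and the list was not called in either case (adjusted p = 0.07 and 0.415). It was -0.19 without cadmium 1 (adjusted p = 4.4e-07) and -0.14 without control 1 (adjusted p = 0.000748). Among 396 ribosomal protein unigenes 0 passed when adjusted over the list alone, against 18 at an unadjusted p under 0.05 and 1 called by DESeq2, and the median was 0.12 (camera adjusted p = 0.0647, and 0.000337 without cadmium 1). Without cadmium 2 the median of log2 CPM differences of the ribosomal list was -0.17. Among 259 unigenes of the virus and other organism list, 1 passed, comp17780_c0 above, and the median was -0.010 (camera adjusted p = 0.809).

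**Figure D2:**
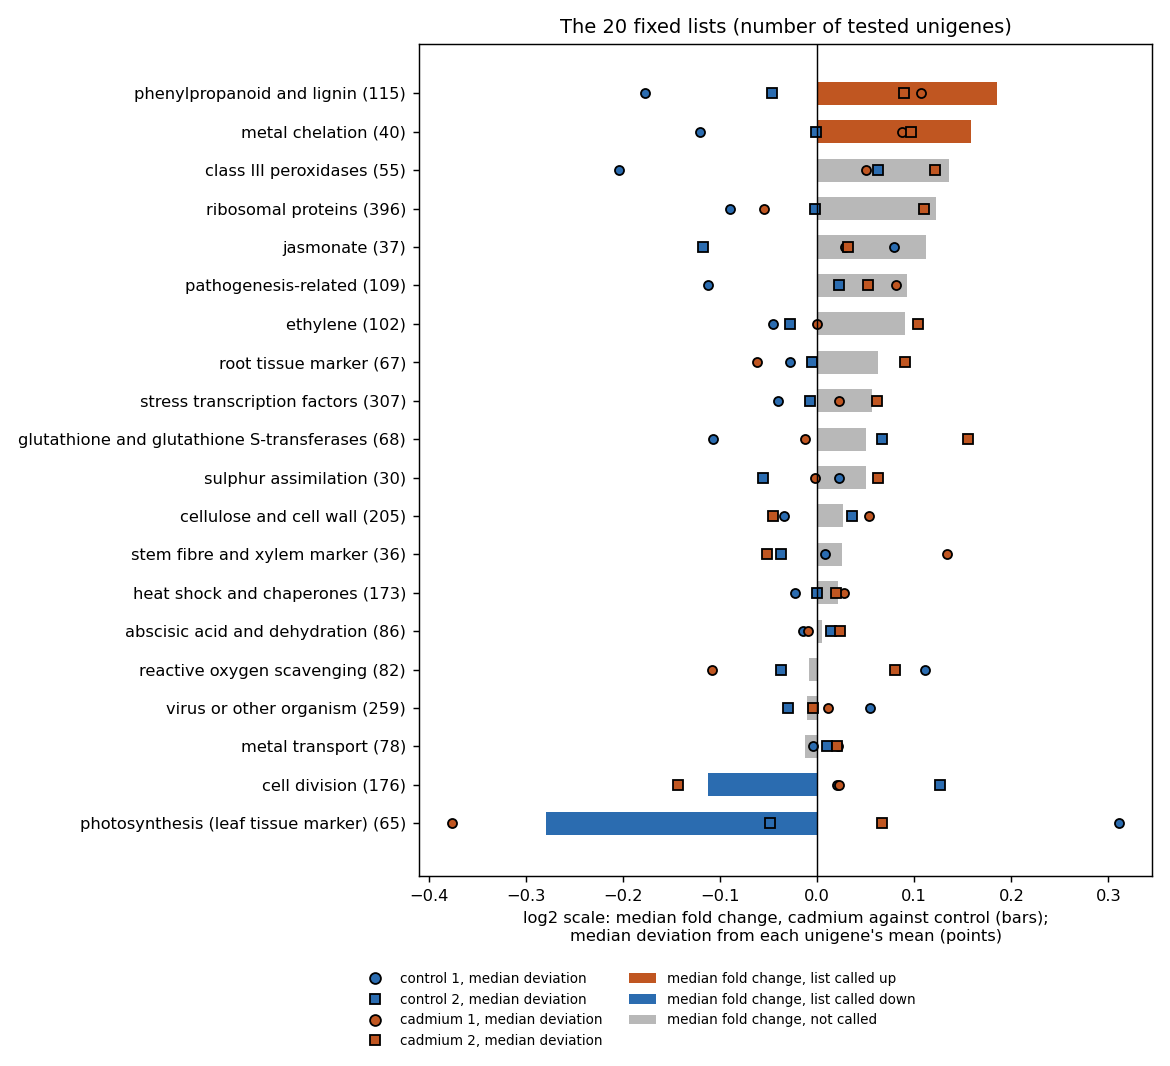
Median log2 fold change of cadmium against control for each of the 20 fixed lists (bars; coloured where camera called the list, grey where it did not), with the median deviation of the list's members from their own means in each library (points, log2 scale). The photosynthesis list has the lowest median, -0.28, and its points run from 0.31 in control 1 to -0.38 in cadmium 1.

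**Figure D3:**
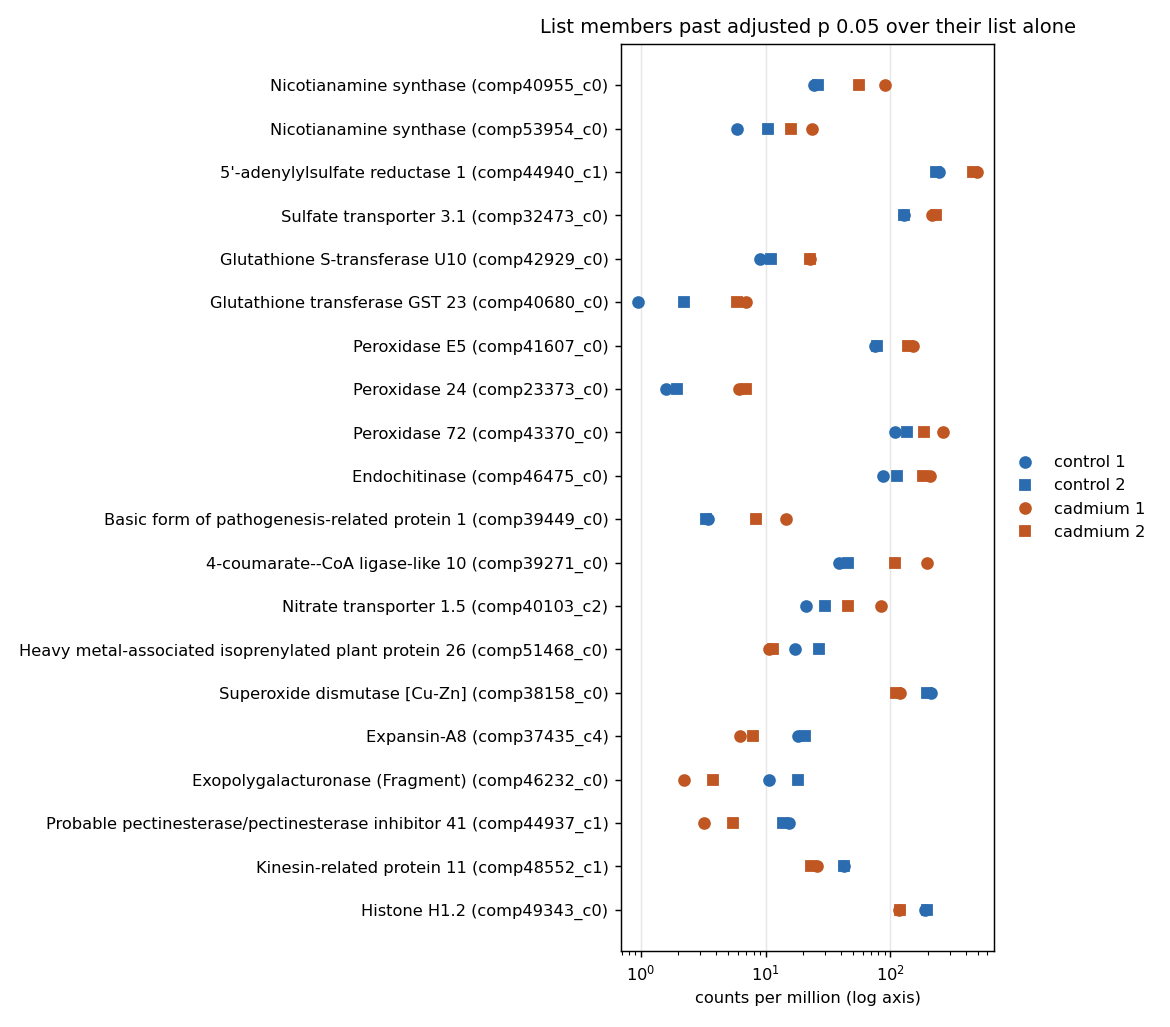
Values in CPM (log axis) in each library of 20 list members that passed when adjusted over their list alone, chosen after their values were seen; circles are plants numbered 1 and squares plants numbered 2. Nicotianamine synthase comp40955_c0 stood at 24.6 and 26.1 in the controls and 89.96 and 56.5 in the cadmium plants.

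Seed storage and oil body proteins were among the unigenes detected in the cadmium plants alone. With a minimum of 10 counts in both libraries of a group and 0 in both of the other, 26 unigenes were seen in cadmium only and 0 in control only. The fold bounds over a floor of 3 counts in the control group ran from 7.9 to 445.2. Legumin A (comp38527_c0), a storage globulin, had 133 and 1045 counts in cadmium 1 and cadmium 2 (at least 445.2-fold higher, and at least 108-fold without cadmium 2), and a 2S albumin (comp32368_c0), a small storage protein, 64 and 594 (at least 248.7-fold higher, and at least 51.9-fold without cadmium 2). Oleosin 1 (comp30956_c0), an oil body coat protein, had 18 and 96 counts, and aquaporin TIP3-2 (comp37550_c0), a water channel of seed vacuoles, 16 and 47. The late embryogenesis abundant unigenes comp35113_c0 and comp33586_c0 and the 18.2 kDa heat shock protein (comp31294_c0) were among the 26 too, with 31 and 25, 21 and 11, and 21 and 81 counts. Without cadmium 1 their bounds were 17.7, 7.78 and 57.3, and without cadmium 2 they were 25.2, 17 and 17. The ratio of cadmium 2 to cadmium 1 per total count ran from 0.32 for a unigene of the fusaric acid resistance family (comp24948_c0) to 10.5 for a universal stress protein (comp35029_c0). Counting intervals and floors cover counting error only, and with a minimum of 5 counts 55 unigenes were seen in cadmium only and 2 in control only, and with a minimum of 20 counts 10 and 0.

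**Figure D4:**
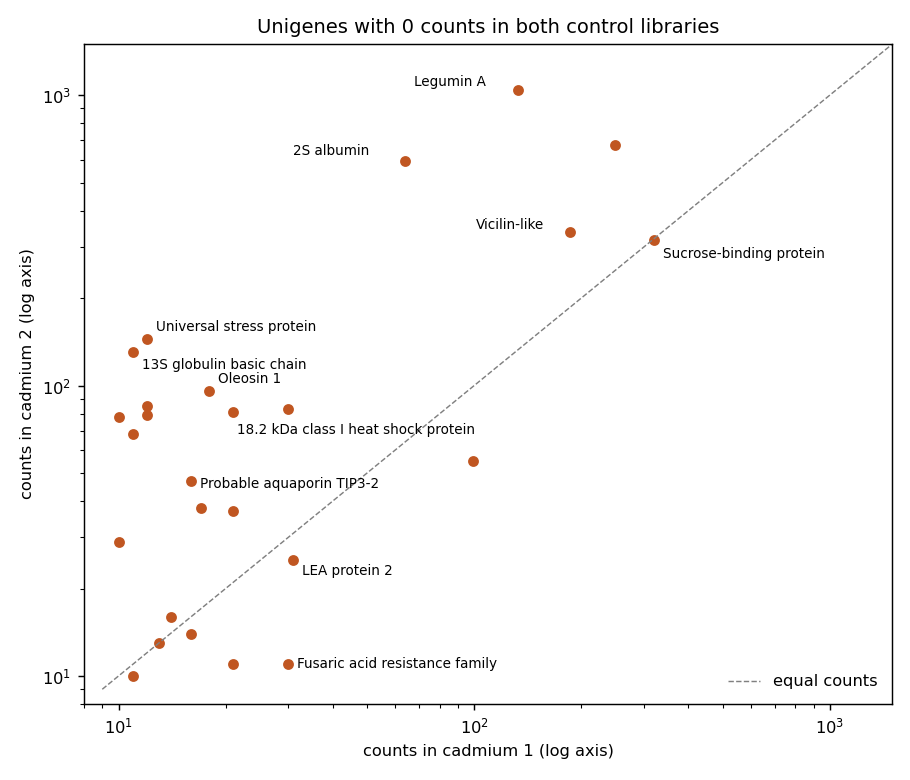
Counts in cadmium 1 and cadmium 2 (log axes) of the 26 unigenes with 0 counts in both control libraries and at least 10 in each cadmium library; the dashed line marks equal counts. Legumin A lies highest, at 133 and 1045 counts, and sucrose-binding protein lies near the line, at 321 and 317.

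Whether plants of a group were more alike than plants of different groups depended on the measure. Across unigenes, which are not independent replicates, Pearson's correlation of log2(CPM + 1) was 0.9937 between the controls and 0.9933 between the cadmium plants, and 0.9905 to 0.9922 between groups. The SD of the log2 difference over tested unigenes was 0.489 and 0.521 within groups and 0.556 to 0.645 between them, and a chi-square per degree of freedom of 15.9 or more for every pair showed no library deposited more than once. Spearman's correlation was 0.8778 between the controls and 0.8791 between the cadmium plants, below the 0.8846 of control 2 with cadmium 1. Pearson's correlation of log2(CPM + 0.1) was 0.9786 for control 2 with cadmium 1, above the 0.9781 and 0.9778 within groups. The chi-square per degree of freedom was 16.03 for control 2 with cadmium 2 and 16.43 between the cadmium plants. By mean expression, the lowest of 5 equal parts of the tested unigenes held 0 calls (edgeR) and the next held 2, both higher in cadmium. By length, 9 of the 16 falls lay among unigenes of 1567 to 2265 bases and 1 among longer ones. Sub-components of the same assembly component had the same sign of change in 59.8% of 5090 pairs, against 49.7% of random pairs matched on expression. Among the 2 pairs with a called member, 0 had the same sign.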

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

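The crossed pairing of plants, the ratios, bounds and seed list median over control counts with a library left out, the count without fungal and arthropod unigenes and the 5 further lists were tests chosen only after the result was seen; the other alternatives were planned. None of the 23 named unigenes and none of the 4 called lists changed direction under the alternatives run. Among lists that were not called, the test direction changed with a library left out for reactive oxygen scavenging, class III peroxidases, ribosomal proteins, glutathione, heat shock, cell wall, stem fibre and virus or other organism. The number of changed unigenes was 32 (16 higher, 16 lower). With DESeq2 it was 461 (232 higher, 229 lower) and with no filter 90 (48 higher, 42 lower), each including all 32. With upper quartile scaling it was 18, with 7 lower, and the lower count was 9 with limma-voom and 9 with library totals. At an adjusted p under 0.01 it was 1 (1 higher, 0 lower). Limma-trend called 0 on log2(FPKM + 1) and 0 on log2(FPKM + 0.1), 0 higher and 0 lower, with 4444 and 4309 of 49077 unigenes at an unadjusted p under 0.05. Leaving out each library in turn gave 112 to 407 changed, 74 to 110 higher and 20 to 315 lower. In those fits the lone plant of a group is assumed to vary like the plants of the other group. Of the 32, 32, 32, 28 and 27 were called without control 1, control 2, cadmium 1 and cadmium 2. Without fungal and arthropod unigenes 40 were called, 32 of them shared. The cause was not tested for any of these differences.

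With the plant number as a block, pairing plants that the labels only number, 13 were called (2 lower), 9 of them among the 32. With the numbers crossed 530 were called (263 higher, 267 lower). Deviations from the group mean in plants of the same number had a correlation of -0.21 across unigenes, which are not independent replicates.

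Of the 23 named unigenes, all kept their direction and the number still past the threshold was 23 with DESeq2, 15 with limma-voom, 13 with upper quartile scaling, 19 with library totals, 22 with robust fitting, 9 with the block and 0 with limma-trend on FPKM. Unigenes seen in 1 group only numbered 57 (55 in cadmium, 2 in control) and 10 with minimums of 5 and 20 counts, against 26, since the minimum itself sets that number. Sub-component pairs of the same sign made up 58.3% at a mean log2 CPM of at least 1. Of the 20 lists, camera called 4, 0 with an estimated correlation, fry 0 (0 at an unadjusted p under 0.05 for both), and 1 to 7 with a library left out. Little can be said of unigenes with few counts: the lowest of 5 equal parts by expression held 0 of edgeR's 32 calls. Whether depth accounts for this was not tested.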

Other observations

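The 5 lists described here and the tests of explanations were chosen only after the results were seen, so their directions are not independent evidence. Adjusted p-values of these lists, and counts of members passing when adjusted over the list alone, describe them only and do not control false calls. Seed storage and oil body unigenes were higher in the cadmium plants: of 19 tested, 17 had a positive log2 fold change and 12 rose when adjusted over the list alone (camera adjusted p = 1.44e-14), and the adjusted p was 0.242 with an estimated correlation. With the 9 members at 0 in both controls set at their bound and the 3 with 1 to 3 control counts at their count ratio, the median was 5.20 on the log2 scale (36.7-fold), and it was 48.1-fold without cadmium 1, 9.74-fold without cadmium 2, 19-fold without control 1 and 17.7-fold without control 2. The other members had more than 3 control counts, such as glutelin type-A 1 (comp45678_c0) at 54.8 and 49.6 CPM in the controls and 63.6 and 56.1 in the cadmium plants. Of 4 tested oleosins, 2 rose when adjusted over the list alone and 2 had a negative log2 fold change, the only negative members. Oleosin 18.2 kDa (comp22257_c1) stood at 0.80 and 2.86 CPM in the controls and 1.26 and 0.75 in the cadmium plants. Over all 19 members the 2 control libraries together held 3534 counts, while cadmium 1 alone held 3015 and cadmium 2 alone held 6777. Legumin B (comp28511_c0), a storage globulin, had 1 count in the controls and 100 and 908 in the cadmium plants, a ratio of 1140 with a 95% counting interval of 205 to 45200. The ratio was 1930 without cadmium 1, 244 without cadmium 2 and 591 without control 1, and without control 2 the level was at least 184-fold higher. Starch synthesis genes were higher as a list (10 of 14 positive, camera adjusted p = 0.00581), and the adjusted p was 0.301 with an estimated correlation and 0.147 without control 2. Members that rose when adjusted over the list alone were the glucose-6-phosphate/phosphate translocator 2 (comp44857_c0), which carries sugar phosphate into plastids, from 132.1 ± 21.9 to 442.1 ± 136 CPM, and 2 subunits of ADP-glucose pyrophosphorylase, the enzyme that makes the glucose donor of starch (comp16042_c1, 1.46, SE 0.22, and comp44943_c0, 0.73, SE 0.18). Flavonoid genes were higher as a list (27 of 35 positive, median 0.29, camera adjusted p = 0.00154), and the adjusted p was 0.301 with an estimated correlation, 0.141 without control 1 and 0.0743 without cadmium 1, where the median of log2 CPM differences was 0.16 and 0.15 against 0.28 with all libraries. Chalcone synthase (comp49246_c0), the entry enzyme of the pathway, rose by 0.88 (SE 0.23) when adjusted over this list alone (adjusted p = 0.041), but its adjusted p was 0.106 over the phenylpropanoid list, which was fixed earlier and holds it too. Of 4 leucoanthocyanidin dioxygenase unigenes comp41317_c0 rose by 0.88 (SE 0.23), comp53779_c0 fell by 1.17 (SE 0.27) and the others did not pass.

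Genes of cutin, wax and surface lipids were lower in the cadmium plants: of 110 tested, 77 had a negative log2 fold change, with a median of -0.42 (camera adjusted p = 2.31e-10), and the adjusted p was 0.301 with an estimated correlation. Over all tested unigenes 6 members fell, and adjusted over the list alone 45 fell and 5 rose, the latter all described as GDSL esterase/lipase 1 or 2, such as comp46030_c0 (1.83). Of 63 GDSL esterase/lipase unigenes in the list, 16 fell and these 5 rose when adjusted over the list alone. Glycerol-3-phosphate acyltransferase 1 (comp44031_c0) fell from 75.6 ± 2.29 to 28.3 ± 3.95 CPM, HOTHEAD (comp42245_c0) by 1.43 (SE 0.18) and fatty acyl-CoA reductase 1 (comp44174_c0), which makes fatty alcohols, by 1.20 (SE 0.15). Cytochrome P450 86A2 (comp46089_c3), a fatty acid hydroxylase of cutin synthesis, fell by 1.09 (SE 0.15) when adjusted over the list alone. Among floral organ identity and MADS box genes, 24 of 37 were negative, with a median of -0.26 (camera adjusted p = 0.0307), and the adjusted p was 0.372 with an estimated correlation. APETALA 1 (comp50197_c0), a gene of flower meristems, stood at 48.4 and 111.1 CPM in control 1 and control 2 and at 28.1 and 17.9 in cadmium 1 and cadmium 2. The floral list was called without control 1 (adjusted p = 0.000149) but not without control 2 (median of log2 CPM differences -0.11, adjusted p = 0.162), cadmium 1 (adjusted p = 0.173) or cadmium 2 (adjusted p = 0.169).

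Of the 19 tested seed storage and oil body unigenes, 9 at 0 and 3 with 1 to 3 counts in the controls were present in both cadmium plants. Lower depth of the controls is excluded, since they held 53.1% of all counts. Reads from 1 outside source carried into both cadmium libraries would keep 1 ratio between them, and the chi-square per degree of freedom of such a ratio over the 26 cadmium-only unigenes was 32.2, which argues against 1 such source for all 26. Outside material that differed between the cadmium libraries, or that gave only some of the 26, was not tested and stays open. A wider abscisic acid and dehydration response cannot be told apart from seed or embryo tissue in the cadmium samples: that list's adjusted p was 0.567, and while 3 late embryogenesis members rose when adjusted over the list alone, its members were split 43 to 43 in sign. Its 10 late embryogenesis abundant members were split 9 positive to 1 negative (median log2 fold change 0.47). Cadmium itself, and seed set on these plants, which the labels do not mention, stay open too and were not tested.

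For cutin, wax and surface lipid genes, the median of log2 CPM differences was -0.405 with all libraries and -0.294 without control 2, so the fall was smaller but remained. The list was written after members had been called in these same 4 libraries, so leaving a library out is not an independent test. The cutin median was -0.432 without control 1 and -0.358 without cadmium 1. The photosynthesis median shrank from -0.285 to -0.085 and -0.086 in the same fits, so the cutin fall did not shrink in step with it. The photosynthesis medians stayed negative and the cutin list was drawn from these data. A lower share of leaf tissue in the cadmium samples can therefore not be decided on. A difference in epidermis, young shoot or flower share and an effect of cadmium may each lie behind the fall of the cutin list, and neither was tested.

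Virus-like unigenes were present in all 4 plants. An RNA2 polyprotein (comp48386_c0) stood at 2765 and 3008 CPM in the controls and 1480 and 2702 in the cadmium plants (adjusted p = 0.675), and an RNA1 polyprotein (comp48924_c0) at 2310 and 1519 against 770.3 and 1687 CPM (adjusted p = 0.654). A potyvirus-like unigene (comp37584_c1) had 327 counts in control 2, 2 in cadmium 2 and 0 in the other libraries. Unigenes matching arthropod genera took 229.6 and 149.3 CPM in the controls and 149.7 and 257 in the cadmium plants, and those matching Agaricomycetes, a class of fungi, 58.3 and 90.9 against 28 and 36.3 CPM. Of 15 tested arthropod and 326 tested Dothideomycetes unigenes edgeR called 0 and 0 and DESeq2 0 and 0, with 1 and 2 at an unadjusted p under 0.05.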
